A study of Mus musculus with 2 samples.

How the data were processed

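CD8 T cells from the colon lamina propria of Rag1 knockout mice were measured by droplet single-cell RNA sequencing with a 10x Genomics 5′ v2 kit and feature barcoding, per the labels' protocols. The mice had received wildtype naive CD4 T cells, which drive colitis in hosts that lack lymphocytes, together with splenic CD8 T cells of Bcl6fl/fl Cd8aCre or of Bcl6fl/fl donors. In these donors loxP sites flank part of the Bcl6 gene, and Cre is made under Cd8a control in the first genotype only. Cells carried 8 hashtag antibodies and were pooled into 1 gene-expression library and 1 hashtag library. With a single pooled library, no difference between capture reactions could separate the groups, and the annotation held no batch column.

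The main table held raw UMI counts per gene and cell as deposited by the authors, 12798 genes by 8562 cells, and its sum per cell equalled the total count annotated for that cell in 100% of cells. The submitters' processing notes named bcl2fastq 2.20.0.422, Cell Ranger 7.0.0, Seurat 4.3.0 and the mm10 build, with no role or order for each tool. The UMAP coordinates in the annotation were scores with no unit, deposited by the authors, and were not used. Cells and genes had been filtered before deposit, as the values show: every cell had at least 500 genes and at most 3.0% mitochondrial UMIs, and every gene was seen in at least 9 cells. No further cell was removed. No doublet caller was run; the hashtag calls of the annotation were taken as they stand, under which 1 of the classifiers had called 32 of the kept cells as 2 hashtags. In all, 115 cells (1.34%) were not given their annotated hashtag by both classifiers, and results without them were computed as an alternative.

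Each cell's hashtag and group came from the donor and condition columns of the annotation. The groups are named Cren and Crep there and in the feature barcode table; they were read as Cre-negative (Bcl6fl/fl) and Cre-positive (Bcl6fl/fl Cd8aCre), a reading that no source spells out, and are called Cren and Crep throughout. Each group had 4 hashtags. The hashtag was the replicate; no source says that each hashtag was a separate mouse, so the p-values measure the spread between hashtags. The total per hashtag ran from 2635241 to 4201265 UMIs. Shares of cells in a single hashtag have 95% Wilson intervals, which cover counting error only; for a count of 0 the limit that 3 counts give is also printed.

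The annotation held 8 coarse clusters (resolution 0.6) and 12 fine ones (resolution 0.9), with an empty cell type column. The coarse clusters were named from marker genes chosen before the data were examined, a marker counting where its CPM was at least 1.5 times that of the other cells and at least 5% of cells had a UMI. Cluster 1 was tissue-resident-like, cluster 2 stem-like, clusters 3 and 4 cytotoxic-like and cluster 5 exhausted-like. Cluster 1 had 3 raised markers each of the tissue-resident and stem-like classes, and was named for Itgae, the 1 marker of either class among its 10 leading genes. Clusters 0, 6 and 7 stayed unnamed, the last with a median of 990 UMIs per cell. Sizes of clusters 0, 1 and 5 were not read as results. The reason was that 2, 2 and 4 of their 10 leading genes passed between the groups over all cells or within a cluster. For clusters 2, 3, 4, 6 and 7 this number was 0. Tcf7, a leading gene of cluster 2, and Havcr2, a leading gene of cluster 4, passed adjusted over their own lists, so the sizes of these clusters are not free of genes that differed.

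The tests, samples, gene lists, naming rule and main alternatives were chosen before the data were examined. Raw UMI counts were summed per hashtag and tested in edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, robust), as Crep minus Cren, with Benjamini-Hochberg adjustment at 0.05. Clusters with at least 20 cells in at least 3 hashtags of each group were tested alike, which left clusters 0 to 3, and the difference of effects between the 2 largest clusters was tested as an interaction with the hashtag as a block. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, whose p tests a shift in 1 direction and whose mixed p tests changes in either direction. Shares of cells and hashtag totals were compared with exact two-sided permutation tests, whose smallest p is 0.0286 for 4 against 4 hashtags. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs with a fixed seed. Expression levels are given as CPM, the UMI counts of a gene scaled to the total of the hashtag, or of its cells in a cluster. That total covers the genes kept by the count filter and is multiplied by the TMM factor. Marker CPM of clusters and Bcl6 levels with clusters weighted equally use plain totals of all genes. Errors are SD over 4 hashtags for CPM and shares and SE for log2 fold changes. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

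The genes named over all cells were Bcl6 and the 12 largest changes in each direction among genes at an adjusted p under 0.05 with an average log2 CPM of at least 4. TCR variable and joining segments, ribosomal, mitochondrial, Gm, Rik and predicted genes were counted but not named. Up to 4 members of each gene list that passed were added, or otherwise the 2 with the smallest p; within clusters the 5 largest in each direction were named. Members named because they passed over their own list, and genes of the interaction, were chosen after their values were seen. The 21 lists covered stem-like memory, cytotoxic effector, tissue residency, inhibitory receptors and exhaustion, cytokines and chemokines, type 17, cell cycle, interferon response, early-response AP-1, heat shock, glycolysis, oxidative phosphorylation, cell death and candidate BCL6-repressed genes, and markers of CD4 T, gamma-delta T, NK and innate lymphoid, B and plasma, myeloid, epithelial and stromal, and erythroid and mast cells. No gene of the erythroid and mast cell list passed the count filter, which left 20 lists tested. Coordinates are from the GRCm38 (mm10) gene annotation, GENCODE release M21.

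The pipeline was tested on simulated counts drawn from the means, totals and dispersions of the real counts. The 200 genes changed all had an average log2 CPM of at least 4, and genes were drawn independently of each other. Recovery is thus not known for genes of lower level or for changes that move many genes together. Over all cells (9521 genes) the pipeline recovered 64.2% of 1.5-fold, 97.0% of 2-fold and 98.5% of 3-fold changes, with 5.46% of calls false. At a 2-fold change it recovered 73.1% in cluster 0, 70.1% in cluster 1, 79.1% in cluster 2 and 65.7% in cluster 3. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and count filters, equal cells per hashtag, median UMIs as a covariate, TCR, ribosomal and mitochondrial genes left out, each hashtag left out, other depths and other statistics for shares. Further ones were added after seeing the data. Some changed the cells: only those called alike by both classifiers kept, or expanded TCR cells, cluster 4 or cluster 7 left out. Expanded TCR cells here are the cells of Crep 4 in cluster 4 and of Cren 3 in fine cluster 10. They were picked by hashtag and cluster, with no TCR segment read, so cells with the same segments elsewhere were kept. Another held the cluster mix fixed, by averaging CPM over clusters 0 to 3 with equal weight. It tested log2 values with limma and left out cells of the other clusters. Others were fine clusters, the hashtag number as a block, and the mixed p of fry. An estimated correlation for gene lists in these settings was added too. Mitochondrial and ribosomal shares were also tested only after their values were seen.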

Results

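The data comprised 8562 CD8 T cells of the colon lamina propria from the T cell transfer model of colitis, with 25614763 UMIs in total. They carried 8 hashtags, 4 in the group labelled Cren (4405 cells, 13327631 UMIs) and 4 in the group labelled Crep (4157 cells, 12287132 UMIs). The Cren hashtags held 1305, 1105, 1095 and 900 cells with 4201265, 3184467, 3301369 and 2640530 UMIs, and the Crep hashtags held 1019, 1091, 1001 and 1046 cells with 3024282, 3476216, 3151393 and 2635241 UMIs. A cell had a median of 2764.5 UMIs, from 658 to 8495. Yield and depth did not separate the groups in exact two-sided permutation tests. Cells per hashtag were 1101 ± 165 in Cren and 1039 ± 39.1 in Crep (SD, n = 4, exact p = 0.571). Median UMIs per cell were 2818 ± 142 and 2738 ± 291 (exact p = 0.714). The exact p was 0.543 for total UMIs and 0.886 for median genes per cell. The median mitochondrial share per cell was lower in 4 of 4 Crep hashtags, at 0.637% ± 0.0149 against 0.739% ± 0.0550 in Cren (SD, n = 4, exact p = 0.0286). The median ribosomal share was 20.05% ± 0.628 in Crep and 22.2% ± 2.49 in Cren (exact p = 0.0571). These p-values are unadjusted.

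Bcl6, the transcriptional repressor targeted in the donors (chromosome 16, 23965052 to 23988852, GRCm38), was higher in the hashtags labelled Crep. Its level was 29.4 ± 3.44 CPM in Crep against 17.6 ± 2.201 CPM in Cren (SD, n = 4), a log2 fold change of 0.75 (SE 0.14, edgeR adjusted p = 0.0293). The Cren hashtags had 16.6, 17.4, 15.6 and 20.7 CPM and the Crep hashtags 31.9, 30.6, 30.9 and 24.3 CPM, so all 4 Crep hashtags lay above every Cren hashtag. These levels rest on 231 Bcl6 UMIs in Cren and 362 in Crep. The 5′ kit counts transcript starts and the values are per gene, with no exon, so Bcl6 UMIs here tell nothing about whether the floxed part was deleted, and every direction given is between groups as labelled. The adjusted p was above 0.05 without Cren 1 (0.117), Cren 2 (0.0520), Crep 1 (0.0788), Crep 2 (0.0774) or Crep 3 (0.0696), with a log2 fold change of 0.70 to 0.83 over all omissions of 1 hashtag.

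The comparison of the groups over all cells asks how CD8 T cells from the donor genotypes differed after transfer. Among the named genes of average log2 CPM of at least 4 that passed over all genes, the largest increase in Crep was in Rexo5, an RNA exonuclease gene (chromosome 7, 119794006 to 119848943), at 43.1 ± 5.94 CPM against 16.3 ± 2.66 CPM (SD, n = 4; log2 fold change 1.40, SE 0.14, edgeR adjusted p = 1.5e-04). Entpd1, which encodes the ectonucleotidase CD39, rose from 32.6 ± 7.88 to 67.5 ± 13.0 CPM (log2 1.04, SE 0.17, adjusted p = 0.0303), and Fgl2, a fibrinogen-like gene, rose from 145 ± 14.6 to 256 ± 41.2 CPM (log2 0.82, SE 0.11, adjusted p = 0.00297). Glrx, the glutaredoxin of the thiol redox system, rose from 156 ± 30.04 to 270 ± 38.8 CPM (log2 0.79, SE 0.14, adjusted p = 0.0425). Other genes of this size were AA467197 (log2 1.33, adjusted p = 0.0115), Tmem163 (1.09, 0.0293), Enpp4 (0.78, 0.0492), the cyclin-dependent kinase inhibitor gene Cdkn2c (0.72, 0.0425), the lysosomal trafficking gene Lyst (0.71, 0.0303), Tmem159 (0.69, 0.0427) and Hid1 (0.66, 0.0425). For each of these genes 4 of 4 Crep hashtags lay above every Cren hashtag. The genes were chosen for their difference between the same hashtags, so this separation adds no support.

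In the other direction, Pdcd1, the gene of the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553), was 3.01-fold lower in Crep, at 27.0 ± 7.42 against 81.7 ± 13.2 CPM (SD, n = 4; log2 fold change -1.59, SE 0.18, edgeR adjusted p = 0.00310). Tgif1, a homeobox repressor of the TGF-beta pathway, fell from 106 ± 15.5 to 60.1 ± 7.98 CPM (log2 -0.82, SE 0.12, adjusted p = 0.00310), and Arntl, the circadian clock factor BMAL1, fell from 23.3 ± 5.34 to 12.1 ± 2.50 CPM (log2 -0.93, SE 0.19, adjusted p = 0.0425). Lower levels also passed for the kinase gene Hipk2 (log2 -0.82, adjusted p = 0.0450), Ehbp1 (-0.75, 0.0121), Gpr146 (-0.75, 0.0425), Lztfl1 (-0.72, 0.0494), Gprin3 (-0.69, 0.0492), the TNF receptor adaptor gene Traf5 (-0.61, 0.0494), Thada (-0.57, 0.0369), Coq10b (-0.52, 0.0427) and the Polycomb gene Rnf2 (-0.48, 0.0494). For each of these 12 genes 4 of 4 Crep hashtags lay below every Cren hashtag, which their choice from the same hashtags favours.

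Of 9653 genes tested over all cells, 59 passed, 33 higher and 26 lower in Crep, and 1076 had an unadjusted p under 0.05. The count was 143 with DESeq2, 37 with limma-voom, 32 with cluster 4 left out of every hashtag and 18 with the cluster mix held fixed. Without 1 hashtag it was 14 (Cren 1 or Crep 2), 24 (Cren 4 or Crep 1), 25 (Crep 3), 31 (Cren 2) or 121 (Cren 3), and 42 without Crep 4. Pdcd1 did not pass with cluster 4 left out (log2 -1.36, edgeR adjusted p = 0.120) or with the cluster mix held fixed (log2 -0.61, limma adjusted p = 0.723).

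**Figure D1:**
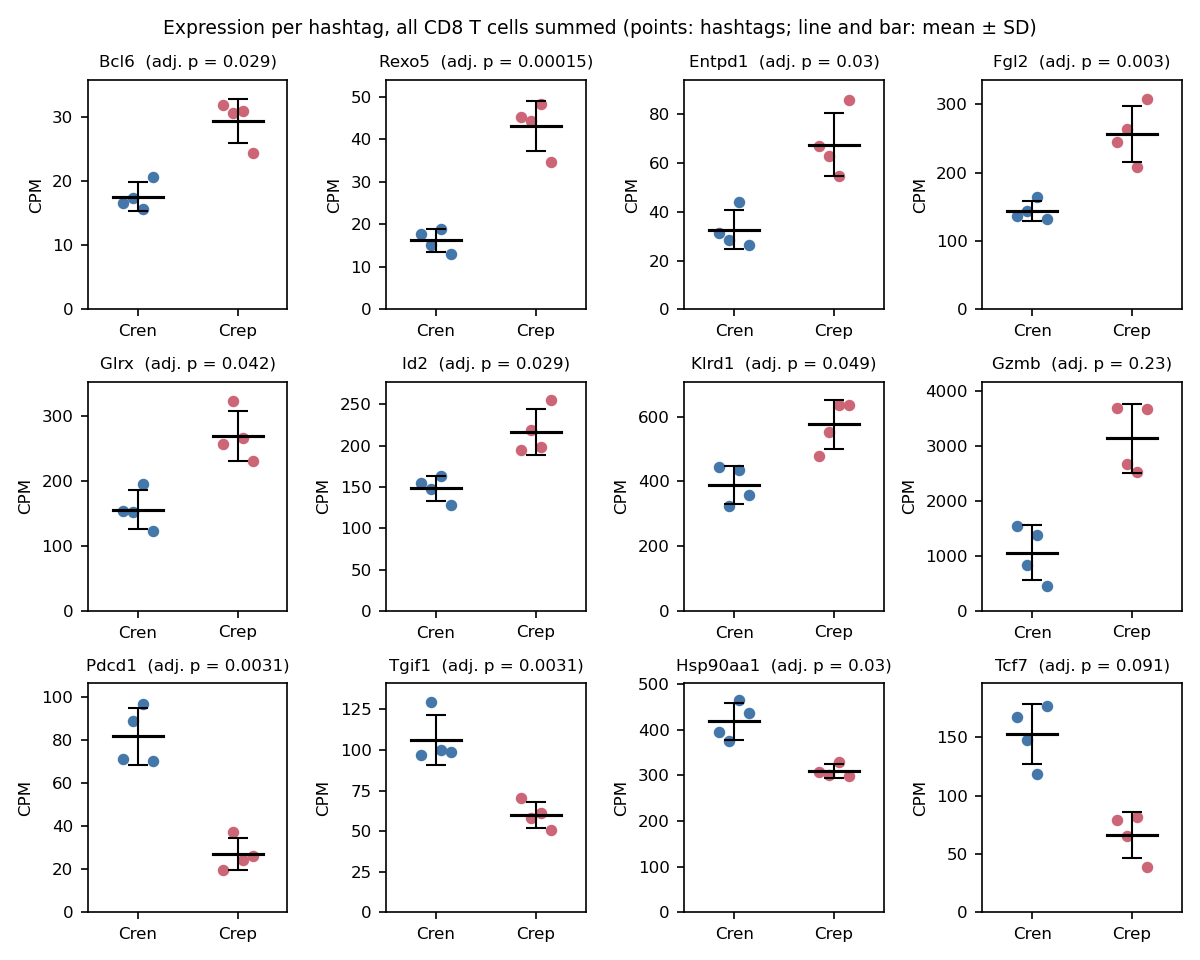
Expression in CPM of 12 genes per hashtag, Cren and Crep side by side; points are hashtags, the line and bar are mean ± SD, and adjusted p-values are from edgeR. Bcl6 lay between 15.6 and 20.7 CPM in Cren and between 24.3 and 31.9 CPM in Crep, while Gzmb and Tcf7 did not pass over all genes.

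Gene lists fixed in advance were compared in the same sums, asking whether programs of CD8 T cell differentiation differed. Cytotoxic effector genes leaned higher in Crep, though few passed singly: 19 of the 20 tested had a positive log2 fold change, with a median of 0.55. The transcription factor Id2 (148 ± 15.2 to 217 ± 28.1 CPM, SD, n = 4, log2 0.54, SE 0.10, edgeR adjusted p = 0.0293) and Klrd1, the gene of the NK receptor CD94 (390 ± 58.5 to 576 ± 75.9 CPM, log2 0.56, SE 0.12, adjusted p = 0.0494), were the 2 that passed over all genes. Adjusted over the list alone, 4 passed, with the granzyme gene Gzmb (1059 ± 502 and 3148 ± 630 CPM, log2 1.57, SE 0.40) and the granule gene Nkg7 (2364 ± 488 and 3342 ± 171 CPM) added. The list passed at the preset correlation (camera adjusted p = 4.8e-13), but not with an estimated correlation (camera adjusted p = 0.235) or with fry in 1 direction (adjusted p = 0.105). As given below, 8 of 35 splits of the hashtags called at least as many lists as the real one. Cluster 4, a cytotoxic-like cluster, held 63.1% of the cells of Crep 4; with cluster 4 left out of every hashtag the camera adjusted p of the list was 9.9e-11 (adjusted p = 0.123 with an estimated correlation), and Klrd1 had an adjusted p of 0.151.

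Stem-like memory genes were lower in Crep as a list, with 14 of 17 tested members negative and a median log2 fold change of -0.36 (camera adjusted p = 1.2e-04; adjusted p = 0.271 with an estimated correlation). Over all genes 1 member passed, and it was Bcl6, which was higher; adjusted over the list alone 4 passed, 1 higher and 3 lower. The lower ones were Tcf7, the gene of the stem-like T cell factor TCF-1 (153 ± 25.7 in Cren and 66.6 ± 19.7 CPM in Crep, log2 -1.19, SE 0.23, edgeR adjusted p over all genes = 0.0914), Id3 (29.5 ± 11.5 and 10.3 ± 4.55 CPM, log2 -1.47, SE 0.36) and the repressor Bach2 (58.5 ± 6.56 and 41.4 ± 8.45 CPM, log2 -0.49, SE 0.13). At 2000 UMIs per cell Tcf7 was detected in 5.50% of Crep 4 cells and in 11.3% to 15.2% in the other Crep hashtags. Cluster 4 held 63.1% of the cells of Crep 4. With cluster 4 left out the list still passed camera at the preset correlation, but not with an estimated one.

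Inhibitory receptor and exhaustion genes went both ways under a call in the lower direction (11 of 16 negative, median -0.48, camera adjusted p = 0.00231; adjusted p = 0.271 with an estimated correlation). Over all genes 2 passed, Pdcd1 lower and Entpd1 higher. Pdcd1 and Tox are leading genes of the exhausted-like cluster 5, at 18.8 and 25.2 times their CPM in other cells. Cluster 5 held 1.31% ± 0.860 of the cells of a Crep hashtag and 10.1% ± 5.90 of a Cren hashtag (SD, n = 4). Its size was not read as a result, since these genes lead it. How far this share accounts for the lower Pdcd1 and Tox levels over all cells was not tested. Adjusted over the list alone 6 passed, with the exhaustion factor Tox (log2 -2.37), the costimulatory receptor Icos (-0.56) and the checkpoint receptor Ctla4 (-0.51) lower and Havcr2, the gene of TIM-3, higher (1.56). Heat shock genes were negative in 10 of 10 (median -0.41, camera adjusted p = 8.5e-09; adjusted p = 0.271 with an estimated correlation). Of these the chaperone gene Hsp90aa1 passed over all genes (418 ± 40.9 to 309 ± 14.3 CPM, log2 -0.43, SE 0.08, edgeR adjusted p = 0.0303), and 6 passed adjusted over the list alone; Hspa1a and Hspa1b are near-identical copies whose counts may be shared. The median mitochondrial share of cells was also lower in every Crep hashtag (0.637% against 0.739%).

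The small type 17 list was negative in 5 of 5 (median -1.02, camera adjusted p = 1.5e-04; adjusted p = 0.165 with an estimated correlation). None of its members passed over all genes, where the nuclear receptor gene Rora came closest (231 ± 39.2 and 139 ± 25.2 CPM, log2 -0.73, edgeR adjusted p = 0.0779) and was the 1 that passed adjusted over the list alone; Maf had a log2 fold change of -1.89 (adjusted p = 0.401). Interferon response genes were positive in 15 of 18 (median 0.17, camera adjusted p = 0.0169; adjusted p = 0.460 with an estimated correlation), with 0 past all genes and 2 adjusted over the list alone, Ly6a (log2 0.57) higher and Ifi27l2a (log2 -1.45) lower. The interferon list did not pass without Cren 2 (0.227) or Crep 4 (0.260). Early-response AP-1 genes were negative in 11 of 14 (median -0.18, camera adjusted p = 0.0317; adjusted p = 0.460 with an estimated correlation), and 0 passed on either scale; Zfp36 (log2 -0.43, edgeR adjusted p = 0.245) and Egr1 (-0.55, 0.448) had the smallest p. The early-response list did not pass with cluster 4 left out (camera adjusted p = 0.410), without expanded TCR cells (0.214), or without Cren 2 (0.110), Cren 3 (0.128) or Crep 4 (0.479). The mitochondrial share, 0.637% in Crep against 0.739% in Cren, was lower alongside it.

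Candidate BCL6-repressed genes were split, with 10 of 16 positive and a median of 0.10 (camera adjusted p = 0.152). Id2 passed over all genes; adjusted over the list alone 7 passed, Id2, Gzmb, Socs2 and Cish higher and Rora, Bach2 and Cd69 lower. With cluster 4 left out the list passed at the preset correlation (camera adjusted p = 0.00777; adjusted p = 0.123 with an estimated correlation). It also passed without expanded TCR cells (0.0301; adjusted p = 0.198 with an estimated correlation).

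The remaining programs did not pass camera at the preset correlation in the test fixed in advance, and some passed in other tests. Cell cycle genes had a median log2 fold change of -0.06 (camera adjusted p = 0.356), with Ccnb2 at -0.96 (edgeR adjusted p = 0.372) and Birc5 at -0.51 (0.581). Cell death genes had a median of -0.09 (0.353), with Bcl2l1 at 0.51 and Bcl2a1d, which shares sequence with near-identical copies, at -0.45. Cytokine and chemokine genes had a median of -0.39 (0.0938), with Ccl4 at 0.45 and Tnfsf8 at -1.34; this list passed without Crep 1 (0.0250). Glycolysis genes had a median of 0.04 (0.123), with Hk1 at 0.35 and Eno1 at 0.25. Tissue residency genes had a median of -0.19 (0.299), with Cd69 at -0.28 and Ccr9 at -0.51. In these 5 lists 0 members passed over all genes and 0 adjusted over the list alone; camera called 0 of the 20 lists with an estimated correlation. For a shift in 1 direction fry called 0, and for changes in either direction it called 11. These were the lists called by camera at the preset correlation other than early-response AP-1, and those of candidate BCL6-repressed genes (adjusted p = 0.00275), CD4 T cell markers (0.00499), glycolysis (0.0164), oxidative phosphorylation (0.0180) and cytokines and chemokines (0.0258). Oxidative phosphorylation genes had a median of 0.08 (0.364), and 1 member passed on both scales, Ndufa4, a respiratory chain gene, which fell from 353 ± 18.5 to 266 ± 19.7 CPM (log2 -0.41, SE 0.08, edgeR adjusted p = 0.0303).

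**Figure D2:**
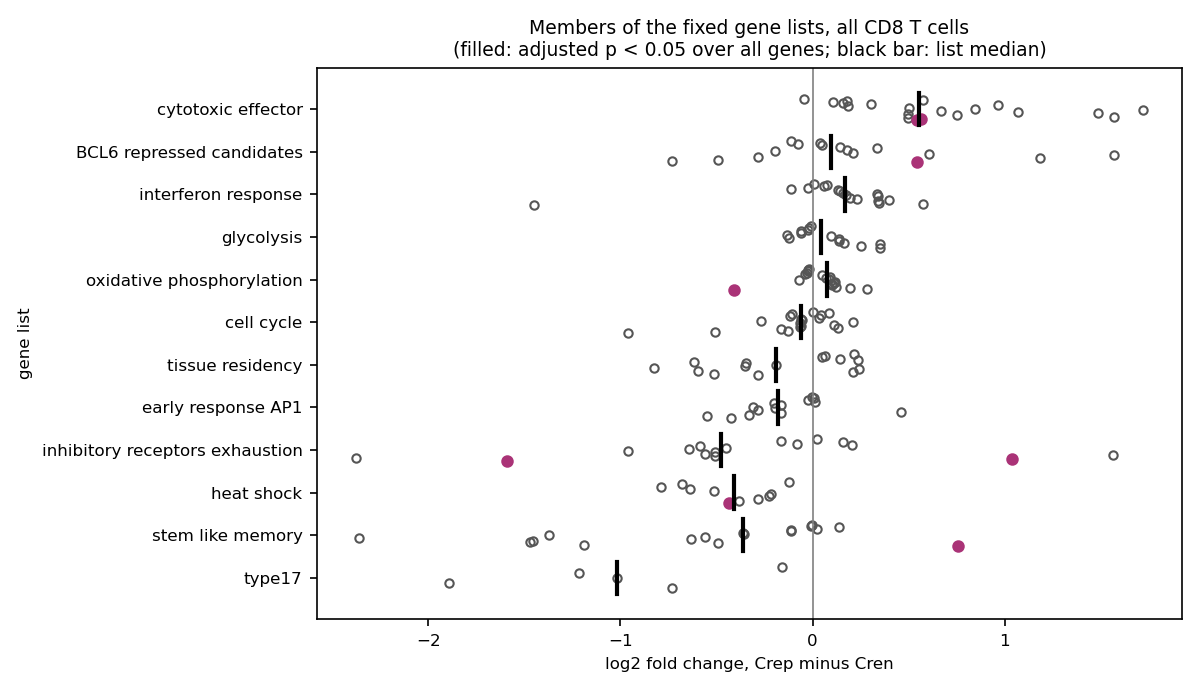
Log2 fold changes, Crep minus Cren, of the tested members of 12 gene lists over all CD8 T cells; each circle is a gene, filled circles passed over all genes, and black bars are list medians. The cytotoxic effector list has 19 of 20 circles right of 0 and the heat shock list 10 of 10 left of 0.

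Markers of other cell types were read for cells that the CD8 T cell isolation might have let through, and the marker that differed was Cd4 (chromosome 6, 124864692 to 124888221). Cd4 was at 6.86 ± 1.54 CPM in Crep and 0.274 ± 0.322 CPM in Cren (SD, n = 4; log2 4.36, SE 0.51, edgeR adjusted p = 5.1e-04). The 4 Cren hashtags had 2, 2, 0 and 0 cells with a Cd4 UMI, where 0 cells, taken as fewer than 3, allow a share of up to 0.274% in Cren 3 and 0.333% in Cren 4 (upper Wilson limits 0.350% and 0.425%), and the Crep hashtags had 17, 28, 19 and 15. Mean shares were 0.0836% in Cren and 1.89% in Crep (exact permutation p = 0.0286), at median depths of 2812 and 2714 UMIs per cell. Of the 79 Crep cells with a Cd4 UMI, 76 (96.2%) also had a UMI of Cd8b1, which encodes the CD8 beta chain, and 0 had one of the CD4 T cell genes Cd40lg or Foxp3.

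The list of 4 tested CD4 T cell markers was not called (camera adjusted p = 0.123); its median was -0.59, its mean 0.38 and its test direction higher. It passed with cluster 4 left out (0.00652; adjusted p = 0.123 with an estimated correlation) and without expanded TCR cells (0.0329; adjusted p = 0.198 with an estimated correlation). It also passed without Cren 1 (0.0270), Crep 2 (0.0346) or Crep 4 (0.0363). Adjusted over the list alone 1 passed, Cd4, while Ikzf2, Tnfrsf4 and Cd40lg did not. Gamma-delta T cell markers had a median of -0.21 (0.558), with Tcrg-C2 at -0.21 (64.8 ± 15.7 and 54.9 ± 23.3 CPM) and Tcrg-C4 at -0.22. NK and innate lymphoid markers had a median of 0.03 (0.988), with Klrb1c at 0.33 and Fcer1g at -0.19. Myeloid markers had a median of 0.06 and a test direction of lower (0.990), with Cd74 at -0.53 (131 ± 25.7 and 90.9 ± 19.2 CPM) and C1qb at 0.41. B and plasma cell markers had a median of -0.64 (0.226), with Ighm at -1.05 and Cd79b at -0.23, and passed without Crep 3 (0.0249). The 1 epithelial and stromal marker tested, Pecam1, had a log2 fold change of -0.75 (0.0811) and passed over the list alone. Its list passed without Cren 2 (0.0105) or Crep 3 (0.0181). Kit was the 1 erythroid or mast cell marker in the table and was not tested. Apart from Cd4, 0 of these markers passed over all genes.

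Shares of cells with a UMI, with every cell thinned to 2000 UMIs, were compared for 8 genes chosen in advance. Gzmb was detected in 87.0% ± 2.33 of Crep cells and 47.4% ± 13.4 of Cren cells (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0762), and all 4 Crep hashtags lay above every Cren hashtag. Tcf7 was detected in 11.2% ± 4.12 of Crep and 24.5% ± 3.35 of Cren cells, and Pdcd1 in 3.62% ± 0.955 and 9.08% ± 1.92, each with an exact p of 0.0286 (adjusted p = 0.0762) and with 4 of 4 Crep hashtags below every Cren hashtag. Slamf6 (2.53% and 6.27%), Gzma (61.1% and 39.8%) and Gzmk (67.2% and 51.0%) each had an exact p of 0.0571, with 3 of 4 hashtags beyond the other group. The integrin gene Itgae (12.2% in Crep and 19.9% in Cren, exact p = 0.257) and the proliferation gene Mki67 (2.57% and 2.86%, exact p = 0.657) overlapped. After adjustment 0 of 8 genes passed the exact permutation test, whose smallest possible p is 0.0286; 3 had an unadjusted p under 0.05.

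Thinning left out 937 Cren and 986 Crep cells. Without it the Crep and Cren shares were 88.6% and 53.0% for Gzmb, 15.4% and 31.1% for Tcf7, 4.90% and 11.8% for Pdcd1, 3.64% and 9.02% for Slamf6, 65.8% and 45.2% for Gzma, 71.0% and 56.9% for Gzmk, 15.3% and 24.4% for Itgae, and 3.89% and 4.42% for Mki67. The table held no cell type that should lack these genes, so the level given by free RNA was not measured.

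Cluster sizes were compared for 5 of the 8 clusters of the deposited annotation. The cytotoxic-like cluster 4, with the killer lectin receptor genes Klra3, Klrg1 and Klre1 among its leading genes, took 23.4% ± 26.5 of the cells of a Crep hashtag and 0.598% ± 0.375 of a Cren hashtag (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0762), higher in 4 of 4 Crep hashtags. Its share was 12.7%, 9.53%, 8.29% and 63.1% in the Crep hashtags. Cluster 6, led by Xcl1 and Tnfrsf9, took 0.475% ± 0.287 in Crep and 3.61% ± 4.62 in Cren (exact p = 0.0286, adjusted p = 0.0762), lower in 4 of 4 Crep hashtags. Cren 3 held 10.5% and the other Cren hashtags 0.889% to 2.07%, and the difference of -3.14 percentage points was -0.843 without Cren 3. For cluster 4 the difference of 22.8 points was 9.56 without Crep 4. The stem-like cluster 2 took 12.8% ± 7.37 in Crep and 27.0% ± 13.3 in Cren (exact p = 0.143), the cytotoxic-like cluster 3 took 17.2% ± 8.68 and 13.0% ± 10.6 (exact p = 0.543), and cluster 7 took 1.13% ± 0.505 and 1.22% ± 0.151 (exact p = 0.714). After adjustment over the 8 clusters 0 passed the exact permutation test, 3 had an unadjusted p under 0.05, and 0 passed on logit shares. In contrast, edgeR on cells per cluster called 3, with a log2 fold change of 5.26 for cluster 4 (adjusted p = 1.0e-06) and -2.89 for cluster 6 (adjusted p = 0.00171). The other was cluster 5, with a smaller share in Crep. Its size was not read as a result because Pdcd1 and Tox are among its leading genes. Tcf7 is a leading gene of cluster 2 and Havcr2 of cluster 4, and both passed between the groups adjusted over their own lists. Cluster 4 cells of all 4 Crep hashtags shared their leading TCR segments, as given below, and may come from shared donor cells. The Crep hashtags may then not be independent replicates. P-values for cluster 4, and for the sums over all cells that hold its cells, would overstate the evidence. A shared donor pool would reach the tests within other clusters too, though sharing beyond cluster 4 was not shown.

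**Figure D3:**
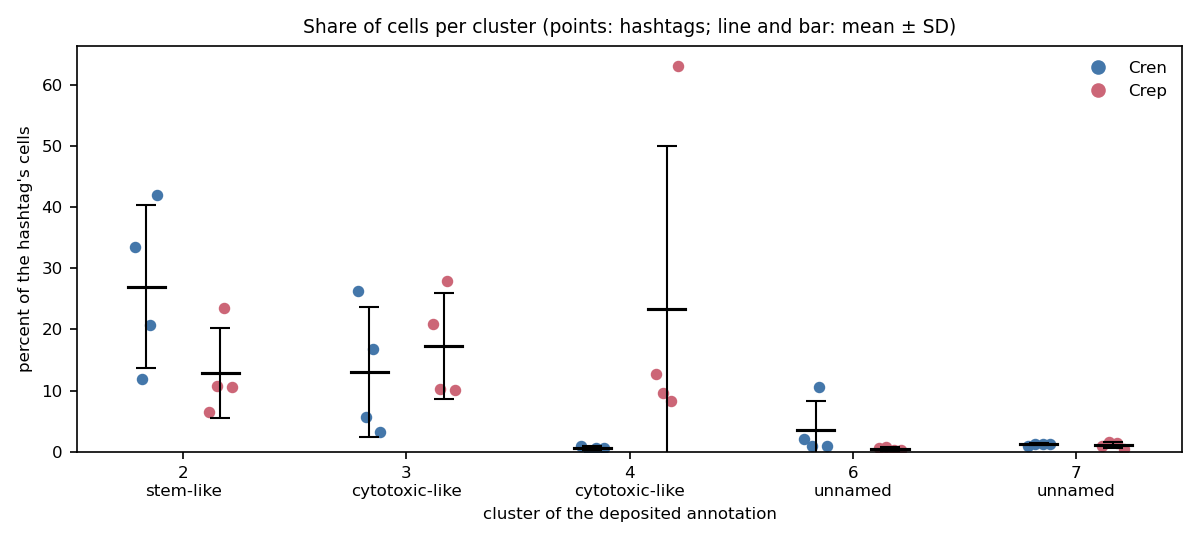
Percent of each hashtag's cells in clusters 2, 3, 4, 6 and 7; points are hashtags and the line and bar are mean ± SD. In cluster 4 the Crep hashtags lie at 8.29%, 9.53%, 12.7% and 63.1%, and every Cren hashtag lies below 1%.

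Cells of cluster 4 used few TCR segments in every Crep hashtag. Trbv13-3 took 68.0%, 64.1%, 58.0% and 81.7% of the Trbv UMIs of the cluster 4 cells of Crep 1 to 4, and Trav19 took 58.0%, 60.7%, 62.0% and 67.7% of the Trav UMIs. In the other cells of the same hashtags Trbv13-3 took 9.50%, 7.10%, 5.39% and 2.57%, and Trav19 took 2.22%, 2.77%, 1.21% and 6.44%. The segments were read from UMIs per gene and hold no CDR3 sequence.

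**Figure D4:**
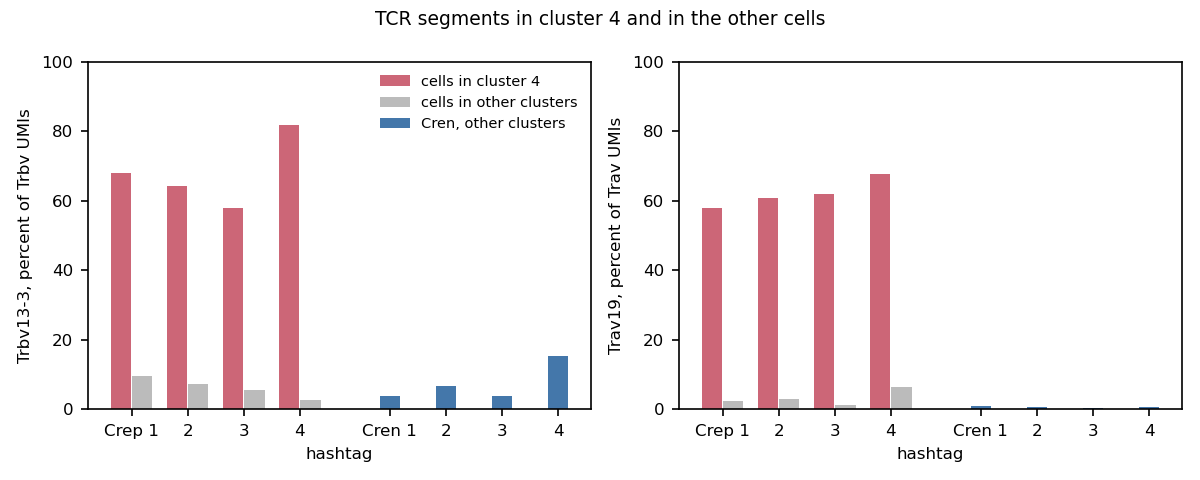
Trbv13-3 as percent of Trbv UMIs and Trav19 as percent of Trav UMIs per hashtag; red bars are cluster 4 cells and grey bars other cells of the Crep hashtags, and blue bars are the Cren cells outside cluster 4. In Crep cells of cluster 4 both segments lie between 58.0% and 81.7%.

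Within single clusters, the comparison asks whether changes over all cells were also seen in cells of 1 state. Rexo5 rose in clusters 0, 1 and 2, by 1.37 (SE 0.26), 2.39 (SE 0.32) and 1.21 (SE 0.27) on the log2 scale, with edgeR adjusted p of 0.0131, 2.8e-05 and 0.0224 and 4 of 4 Crep hashtags above every Cren hashtag. Glrx rose in the same clusters, by 0.69 (SE 0.13), 0.97 (SE 0.13) and 0.85 (SE 0.15), with edgeR adjusted p of 0.0131, 2.8e-05 and 0.00281. Of the genes called over all cells, 49 of 49 measured in cluster 0, 45 of 47 in cluster 1, 44 of 46 in cluster 2 and 43 of 46 in cluster 3 had the direction seen over all cells, which is no independent test, since these cells are part of the whole. Bcl6 had a log2 fold change of 0.84 in cluster 0, 0.81 in cluster 1 and 0.80 in cluster 2, and did not pass there (edgeR adjusted p 0.290, 0.334 and 0.461). Pdcd1 had -0.30, -0.25, -0.89 and -1.29 in clusters 0 to 3 and did not pass either.

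In cluster 0, 11 of 6338 genes passed, 6 higher and 5 lower in Crep. The stress-response gene Sesn1 rose from 11.0 ± 3.00 to 33.6 ± 5.82 CPM (SD, n = 4, log2 1.41, SE 0.30, edgeR adjusted p = 0.0293). Lower were Lmo1 (log2 -1.34), Phlda1 (-1.09), Thada (-0.88, 3 of 4 hashtags beyond the other group), the T cell receptor modulator Cd5 (194 ± 38.9 to 117 ± 23.4 CPM, log2 -0.82, SE 0.15, adjusted p = 0.0131) and Sh2d1a, the gene of the SLAM adaptor SAP (206 ± 11.1 to 131 ± 20.3 CPM, log2 -0.61, SE 0.12, adjusted p = 0.0180). The count was 1 without Crep 3, 4 without Cren 2, and 6 without Cren 3 or Crep 2.

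In the tissue-resident-like cluster 1, 13 of 5817 genes passed, 11 higher and 2 lower. The chemokine receptor gene Ccr2 rose from 13.1 ± 6.66 to 71.9 ± 31.2 CPM (SD, n = 4, log2 2.32, SE 0.31, edgeR adjusted p = 2.8e-05), and Socs2, a suppressor of cytokine signalling, rose from 20.1 ± 4.08 to 58.1 ± 13.4 CPM (log2 1.71, SE 0.25, adjusted p = 9.1e-05). The phosphoinositide 3-kinase subunit gene Pik3r5 (log2 1.43) and the NADPH oxidase gene Ncf1 (1.03) were also higher. Tox fell from 33.3 ± 5.89 to 11.2 ± 5.61 CPM (log2 -1.61, SE 0.37, adjusted p = 0.0486), and the RNA-binding gene Zfp36l1 fell by 0.60 on the log2 scale. The count was 6 without Crep 3, 8 without Crep 1, 21 without Cren 2 and 26 without Cren 3.

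In the stem-like cluster 2, 41 of 5757 genes passed, 20 higher and 21 lower. The actin-capping gene Capg rose from 89.0 ± 4.76 to 278 ± 80.1 CPM (SD, n = 4, log2 1.69, SE 0.15, edgeR adjusted p = 4.2e-09), and Rcn3 (27.8 ± 7.43 to 60.4 ± 16.4 CPM), AA467197 (log2 1.19, 3 of 4 hashtags beyond the other group) and Lcn4 (log2 0.95) were also higher. Trat1, a TCR-associated adaptor gene, fell from 80.7 ± 27.0 to 34.95 ± 3.899 CPM (log2 -1.22, SE 0.25, adjusted p = 0.0149), and the aryl hydrocarbon receptor gene Ahr fell from 45.9 ± 6.25 to 20.4 ± 9.32 CPM (log2 -1.14, SE 0.28, adjusted p = 0.0336). Ifi27l2a (log2 -1.06, 3 of 4 hashtags beyond the other group), Csrnp1 (-1.02) and Sertad1 (-1.01) were also lower. The count was 10 without Crep 3, 11 without Cren 2, 15 without Crep 1, 19 without Crep 2, 23 without Cren 4, 26 without Cren 1 and 85 without Cren 3.

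In the cytotoxic-like cluster 3, edgeR called 0 of 5489 genes, with 297 at an unadjusted p under 0.05; no other tool was run within clusters. The count was 2 when hashtags needed at least 50 cells, and 1 (without Crep 3) to 8 (without Crep 4) with a hashtag left out.

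The difference of effects between clusters 0 and 1, tested as an interaction, passed for 4 of 6627 genes. Ccr2 was higher in Crep by 2.32 in cluster 1 and 0.42 in cluster 0 on the log2 scale, a fitted difference of 1.84 (SE 0.33, edgeR adjusted p = 0.0111). The RNA-binding gene Zfp36l2 had 0.30 in cluster 1 and -0.23 in cluster 0, a fitted difference of 0.57 (SE 0.11, adjusted p = 0.0111). The others were the TCR segments Trbv20 (2.25) and Trav14-3 (3.19). These 4 were named after their values were seen; limma-voom called 1 gene.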

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

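Tests chosen only after the result was seen were those of free RNA and CD4 T cells for Cd4, those of the 3 explanations for Bcl6, both tests for the clusters held mostly by 1 hashtag, and the splits of the hashtags; the doublet test for Cd4 was set before.

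Cd4 UMIs appeared in 79 Crep cells and 4 Cren cells. Free RNA in the pooled suspension would reach cells of both groups alike, whereas the share of cells with a Cd4 UMI was 20.9-fold higher in Crep. CD4 T cells among the isolated cells would lack Cd8b1, which was present in 96.2% of these cells against 88.3% of other Crep cells. Of these cells 0 held Cd40lg or Foxp3, although Tnfrsf4, another marker on the CD4 T cell list, was in 5.06% against 0.981%. The share with Cd8b1 that free RNA gives was not measured. Cd40lg and Foxp3 were in only 1.01% and 0.172% of other Crep cells, so their absence is weak evidence against CD4 T cells. Doublets of a CD4 and a CD8 T cell would hold more UMIs, but the median was 3265 UMIs, under the 75th percentile (3325) of 885 control genes seen in a like number of cells. A difference by genotype may underlie the pattern and stays open, since nothing beyond the group labels was available to test it.

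Bcl6 was higher in Crep although its gene was the one targeted. A different make-up of the clusters was argued against by a log2 difference of 0.95 (SE 0.11, exact permutation p = 0.0286) with clusters 0 to 3 weighted equally. An exchange of 1 hashtag label between the groups would put 1 hashtag of each group in the range of the other. Instead 4 of 4 Crep hashtags lay above every Cren hashtag, but this is the pattern itself and no separate test of the labels. An exchange of the whole groups cannot be told apart from the labels as given, because the difference of 11.8 CPM comes from counts per gene that show no exon. A transcript that is still made from the recombined gene could also give such counts and was not tested.

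A pair of clusters came mostly from 1 hashtag: Crep 4 gave 660 of 1003 cells of cluster 4, and Cren 3 gave 109 of 112 cells of fine cluster 10. Expanded T cell clones would share TCR segments, and Trbv13-3 took 81.7% of the Trbv UMIs of the first and Trbv2 took 91.8% of the second, against 2.57% and 0.927% in the other cells of the same hashtags. The cells of these clusters were not shallower than the other cells of the same hashtag, with medians of UMIs 1.02 and 1.11 times theirs. This comparison cannot see a hashtag that is shallow as a whole. Crep 4 had a median of 2334 UMIs per cell, against 2729 to 2997 in the other Crep hashtags. Expansion of few clones may thus have shaped both clusters, but segment use is not a clone call, and the genotype was not tested as a cause.

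With 4 hashtags per group, single hashtags lay far from the rest of their group in 9 of 148 groups of values tested (6.08%), where chance gives about 1 in 20. Cluster 4 took 63.1% of Crep 4 and 8.29% to 12.7% of the other Crep hashtags. Cluster 6 took 10.5% of Cren 3 and 0.889% to 2.07% of the other Cren hashtags. At 2000 UMIs, Mki67 was detected in 4.497% of cells of Cren 3 and in 2.204% to 2.45% elsewhere in Cren. Bcl6 stood at 24.3 CPM in Crep 4 and at 30.6 to 31.9 CPM in the other Crep hashtags. Tgif1 stood at 129 CPM in Cren 2 and at 97.0 to 99.7 CPM in the other Cren hashtags. Ehbp1 stood at 25.8 CPM in Crep 4 and at 38.3 to 40.3 CPM in the others. Ccnb2 stood at 1.53 CPM in Cren 4 and at 5.71 to 6.22 CPM in the others. Ifi27l2a stood at 34.96 CPM in Crep 4 and at 66.3 to 68.6 CPM in the others. Ndufa4 stood at 296 CPM in Crep 3 and at 255 to 259 CPM in the others.

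The difference of the Crep minus Cren effect between clusters 1 and 0 passed the interaction test for 4 genes: Trbv20 (2.25), Ccr2 (1.84), Zfp36l2 (0.57) and Trav14-3 (3.19). Of 35 splits of the 8 hashtags, 2 gave as many genes, the highest other split also giving 4, so chance could not be excluded.

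The same 35 splits were run for the other models. Over all cells the real split gave 59 genes and the highest other 4, so 1 split gave as many, the real one. In cluster 0 the real split gave 11 and the highest other 5, and in cluster 2 it gave 41 and the highest other 15, each with 1 split as large. In these models the real split ranked first of 35, the smallest share the test can give. The other splits mix hashtags of both groups, which adds to their spread. Ranking first thus sets the real split apart from the others but does not exclude chance. In cluster 1 the real split gave 13 genes and the highest other 14, with 2 splits as large, so chance could not be excluded. In cluster 3 the real split gave 0 genes and the highest other 7; all 35 splits must reach a count of 0, so this says nothing about chance. For the gene lists 8 of 35 splits called at least the 7 lists of the real one, the highest calling 10, so chance could not be excluded. A real split that ranks first does not separate genotype from anything else that the hashtags of a group share, such as a donor pool.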

How the results depend on the processing

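The alternatives chosen only after the data were seen were those on hashtag calls, expanded TCR cells, clusters 4 and 7, the cluster mix, fine clusters, the replicate block, the estimated correlation in these settings, the mixed p of fry, and the tests of mitochondrial and ribosomal shares. In simulated counts 64.2% of 1.5-fold and 97.0% of 2-fold changes were recovered over all cells, among changed genes of average log2 CPM of at least 4. Of the 28 named genes called over all cells besides Bcl6, 0 turned direction in 23 settings. Expanded TCR cells, as defined above, were picked by hashtag and cluster, not by TCR segments. Calls kept numbered 18 with limma-voom, 16 with median UMIs as a covariate, 19 without expanded TCR cells and 13 with cluster 4 left out. They numbered 7 with the cluster mix held fixed, 21 with the hashtag number as a replicate block and 7 to 24 without 1 hashtag. Rexo5, Tgif1 and Cd4 kept their calls in all 23. Alternatives that leave out clusters of other cell types or cycling cells, or that block on a batch, could not be run, as no such cluster or column existed. Causes were not tested.

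Over all cells 59 genes passed, against 143 with DESeq2, 37 with limma-voom, 32 with cluster 4 left out (20 shared), 18 with the cluster mix held fixed (11 shared) and 103 with the hashtag number as a replicate block (49 shared). No source says that the numbers pair the hashtags. Correlations of hashtags with the same number were -0.0760, 0.216, 0.193 and 0.170, and the highest of all pairs was between Cren 2 and Crep 1 (0.249), so not every hashtag correlated best with its own number. Without 1 hashtag the count ran from 14 to 121: 14 without Cren 1, 31 without Cren 2, 121 without Cren 3, 24 without Cren 4, 24 without Crep 1, 14 without Crep 2 and 25 without Crep 3. The log2 fold change of Bcl6 ran from 0.70 to 0.83, at 0.72 without Cren 1 (edgeR adjusted p = 0.117), 0.75 without Cren 2 (0.0520), 0.72 without Crep 1 (0.0788), 0.73 without Crep 2 (0.0774) and 0.73 without Crep 3 (0.0696).

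Within clusters, leaving out 1 hashtag gave 1 to 15 genes in cluster 0 (4 without Cren 2, 6 without Cren 3, 6 without Crep 2, 1 without Crep 3) and 6 to 26 in cluster 1 (21 without Cren 2, 26 without Cren 3, 8 without Crep 1, 6 without Crep 3). It gave 10 to 85 in cluster 2 (26, 11, 85 and 23 without Cren 1 to 4, and 15, 19 and 10 without Crep 1 to 3) and 1 to 8 in cluster 3 (4, 7, 5 and 2 without Cren 1 to 4, and 6, 3, 1 and 8 without Crep 1 to 4). Cluster 3 gave 2 with at least 50 cells per hashtag. The interaction gave 1 gene with limma-voom. Lists called numbered 0 with an estimated correlation, 0 with fry in 1 direction, 11 with fry in either direction and 6 to 9 without 1 hashtag, against 7. They numbered 10 with the replicate block, 8 with cluster 4 left out and 8 without expanded TCR cells, and 0 in each of these with an estimated correlation. The block added cytokines and chemokines (adjusted p = 0.0130), B and plasma (0.0289) and epithelial and stromal markers (0.0453) and took none away. Leaving out cluster 4 or expanded TCR cells added the CD4 T and BCL6-repressed lists and took away early-response AP-1. Cytokines and chemokines also passed without Crep 1 (0.0250), B and plasma markers without Crep 3 (0.0249), and epithelial and stromal markers without Cren 2 (0.0105) or Crep 3 (0.0181). For cluster shares edgeR called 3 against 0 by the exact permutation test, and without 1 hashtag the exact test gave 0 for cluster shares and 0 at fixed depth, where 4 against 3 hashtags allow no p under 0.0571.

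Values that turned direction had passed in neither setting. With cluster 4 left out, the log2 fold changes were 0.0167 for Cd79b, 0.0412 for Tcrg-C4 and -0.00262 for Klrb1c, and the adjusted p of the NK and innate lymphoid list was 0.217. With the cluster mix held fixed they were 0.208 for Cd79b, 0.0121 for Tcrg-C2, 0.274 for Tcrg-C4 and -0.317 for Klrb1c. That list turned also with the replicate block (adjusted p = 0.987) and without expanded TCR cells (0.526), and with an estimated correlation in these 3 settings (0.991, 0.678 and 0.595, the last with cluster 4 left out). Over all omissions of 1 hashtag, log2 fold changes ran from -0.560 to 0.0672 for Cd79b (positive without Cren 3), from -0.473 to 0.0169 for Tcrg-C2 (positive without Crep 4) and from -0.459 to 0.121 for Tcrg-C4 (positive without Cren 2, at 0.0934, or Crep 4). The adjusted p of lists that turned in some omissions ran from 0.323 to 0.898 for gamma-delta T, 0.343 to 0.956 for myeloid and 0.479 to 0.993 for NK and innate lymphoid markers. Crep minus Cren ran from -0.233 to 0.127 percentage points for the share of cluster 7 (positive without Crep 4) and from -0.632 to 0.257 for that of Mki67 (positive without Cren 3, or at 0.00122 without Crep 2), and the latter was 0.164 at 1000 UMIs.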

Other observations

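The test of sharing with cluster 4 left out, like those of donor sharing, segment diversity and gene position, was set before its result was seen, and the values of single segments and pairs were chosen after.

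Each hashtag had its own leading pair of TCR segments among cells with UMIs of both chains. The leading pair was Trav9-2 with Trbv14 in Cren 1 (8.82% of such cells), Trav14-3 with Trbv3 in Cren 2 (13.5%), Trav3-3 with Trbv14 in Cren 3 (11.1%) and Trav8n-2 with Trbv13-3 in Cren 4 (20.3%). In Crep it was Trav2 with Trbv19 in Crep 1 (14.6%), Trav4-3 with Trbv19 in Crep 2 (8.31%), Trav12-1 with Trbv19 in Crep 3 (7.06%) and Trav19 with Trbv13-3 in Crep 4 (37.8%). The pair of Trav19 with Trbv13-3 was present in cluster 4 of every Crep hashtag, in 50 of 99, 42 of 84, 32 of 65 and 281 of 508 cells with both chains. Outside cluster 4 it was in 8 of 613, 1 of 662, 2 of 643 and 5 of 249 such cells of these hashtags. In Cren 1 cell held the pair, and that cell lay in cluster 4, in Cren 4.

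Crep cells with a Cd4 UMI lay in several clusters, with 4.42% of the Crep cells of cluster 1, 2.46% of cluster 2, 2.30% of cluster 0, 0.922% of cluster 4 and 0.282% of cluster 3. Of these cells 5 had more than 1 Cd4 UMI.

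Hashtags of a group may share donor cells. The mean overlap of TCR segment pairs (Morisita-Horn, 5726 cells) was 0.144 within groups and 0.0298 between them. Of 35 splits 1, the real one, gave a difference as large (real 0.114, highest other 0.0386). That is the smallest share the test can give and does not exclude chance. The overlap of Trbv segments alone was 0.654 within and 0.603 between groups, and 2 of 35 splits gave a difference as large (real 0.0516, highest other 0.0572). The overlap of pairs was 0.241 within Crep and 0.0465 within Cren. With cluster 4 left out it was 0.0463 within and 0.0355 between groups, and 3 of 35 splits gave a difference as large (real 0.0108, highest other 0.0140), so chance could not be excluded and sharing beyond cluster 4 was not shown.

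A difference in Trbv diversity between the groups was not seen: the effective number of segments was 13.3 ± 2.03 in Cren and 12.6 ± 2.93 in Crep (SD, n = 4, exact permutation p = 0.657). Another strain's chromosome segment carried along with the Cre gene would put called genes close together. The largest number of called genes in a window of 20 megabases was 4 (Arntl, Rexo5, Tmem159 and Itgal on chromosome 7), and 70.3% of 10000 random draws of as many genes had a window with at least as many. The draws had a median of 4 and a 95th percentile of 5 called genes in the window. A segment that moves 4 genes or fewer could thus not be seen by this test, and such a segment stays open. Rexo5 (end at 119848943) and Tmem159 (start at 120102353), both higher in Crep, lie close together.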
